A study of Rattus norvegicus with 20 samples.

How the data were processed

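The samples were laser-captured cortical neurons of 10 rats aged 2 years, hybridised on 20 Agilent arrays of 1 design with a red and a green channel. Per the labels' protocols, total RNA of about 300 neurons per cell type went through 2 rounds of T7 amplification and indirect labelling with Cy dyes. The labels give the animal, day, dyes and cell types of each array. The 2 arrays of an animal carry the same RNA pair with the dyes exchanged and were counted as 1 replicate, so n was 5 animals per day. The days are separate cohorts.

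Each array had 43628 spots, 2256 of them controls. Images had been quantified with Agilent Feature Extraction, per the submitters' processing notes, in version 9.1.3.1 per the file headers. The mean and background intensity of each spot were deposited on a linear scale as Feature Extraction wrote them, per the file headers, and were used with the flags for spots well above background, saturated or outlying. The deposited log10 ratio of the red over the green processed signal, which carries Feature Extraction's own background and dye correction per the file headers, served as an alternative. The authors' deposited table holds log2 red over green ratios, and its normalization is not given in the sources used here. Its scale and direction were found by setting each column against that array's own values across probes. Against the loess values used here the correlation was 0.900 to 1.00 with slopes of 0.864 to 1.64, nearer to log2 than to log10 but not a fixed scale, against Feature Extraction's ratios the correlation was 0.101 to 0.875, and each of the 20 columns matched its own array best. Column medians were 0.00338 to 0.0153 and up to 2332 values were missing. How the columns were centred stays unknown. A further 20 columns of that table were not used.

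Background was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3 with the data.table package, version 1.17.8, followed by loess within each array with control spots at weight 0. Spots marked as outliers (11 to 4088 per array) were set to missing, saturated spots were kept, and spots of 1 probe were averaged. Ratios were turned so that positive values mean a higher signal in sprouting neurons. A probe was tested if it was well above background on both arrays of at least 3 animals of 1 day in the channel of 1 cell type, which 34231 of 41012 probes were. For each gene the probe with the highest mean intensity was taken, and probes with no gene name stood alone, giving 31450 features, 11706 of them with a gene name. Probes were named by accession (10658), symbol (4632) or synonym (1119) through a RefSeq table of the GRCr8 assembly, 173 kept the file's name and 24430 had no name here. Coordinates are left out, since the labels and array files name no genome build. Other probes of the named genes had the sign of the probe used in 19 of 27 cases at day 7 and 10 of 19 at day 21.

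The test was limma's lmFit and eBayes on 1 value per animal with both days in 1 fit, contrasts for day 7, day 21, their difference and their mean, and Benjamini-Hochberg adjustment at 0.05. Within 1 day a two-sided exact sign-flip test over 5 animals cannot go below p = 0.0625. Simulated data of 31450 features held 200 genes changed at day 7 and another 200 changed at both days. The spread was the residual one of the fit over both days, scaled to that of each animal. Of the genes changed at day 7 alone, limma recovered 82.1% of those changed by 0.5 on the log2 scale. It recovered 92.5% of those changed by 1 and 100% of those changed by 2, with 8 unchanged genes called. For the mean of both days it recovered 85.1% of genes changed by 0.5 and 100% of those changed by 1. The simulated genes were independent of each other, unlike real ones. With fewer changed genes the adjustment is stricter, so these shares hold for this number of changed genes only. A simulated list of 75 genes shifted by 0.16 gave p = 1.27e-40 in limma's camera, and 4.5% of 200 random lists had p under 0.05. That size and shift are those of the real ribosomal list at day 7, with 75 genes tested and a mean of 0.16. The real list had an estimated correlation between genes of 0.518, so the 4.5% from independent genes does not hold for such lists.

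The 26 gene lists covered regeneration-associated genes, growth inhibitors, axon guidance, growth factors, cytoskeleton and axonal transport, presynaptic genes, glutamate and GABA receptors, voltage-gated channels, immediate early genes, inflammation, chromatin regulators, heat shock, oxidative phosphorylation, ribosomal proteins, extracellular matrix, apoptosis, markers of astrocytes, oligodendrocytes, microglia, endothelium, blood cells, interneurons, glutamatergic neurons, upper and deep layers, and 5 candidates recalled from the study. Of their 975 genes 840 were tested. Each list was tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. A missing value took the mean of the animals of the same day; this replaced the mean of all animals after the list results had been seen, and moved the astrocyte list at day 21 from adjusted p = 0.0478 to 0.0593 in limma's camera. Median, mean and test of a list differed in sign for 10 lists at day 7, 5 at day 21, 4 for the difference and 7 for the mean of both days, none of which passed.

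Genes were named by a rule. Per day it took the 10 largest rises and the 10 largest falls past the threshold with 1 sign in all 5 animals, filled up to 6 per direction by smallest unadjusted p where fewer passed. For the difference and the mean of both days the numbers were 5 and 3. Genes used to fill up also needed 1 sign in all 5 animals of the day, or in all 10 for the mean. The difference had no such condition. From each list it took up to 4 members past the threshold on that day, or, with fewer than 2, the members of smallest p until 2 were named, and it always took the 5 candidates. Symbols that are locus numbers, sequence tags or clone names were skipped, and 2 members of the lists are not reported here. Alternatives covered background correction, Feature Extraction ratios, the authors' table, scale normalization, filters, probes per gene, the animals in the fit, dye orientation, array weights, moderation, the threshold, left-out animals, scan batch and the replicate number as a block. The lists, this rule, the tests and these alternatives were fixed before the data were examined, apart from those named as chosen later. Scans fell into 5 batches, of which 1 held both days. Figures were drawn with matplotlib 3.10.9 under python 3.11.15.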

Results

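The data were 20 Agilent arrays with a red and a green channel, from 10 rats aged 2 years, 5 animals at day 7 and 5 separate animals at day 21. In each rat a pair of fluorescent cholera toxin B tracers had been injected at 1 site in the cortex beside a stroke. The later tracer followed after a survival period of 7 days in one cohort and 21 days in the other, which names the days, and about 300 neurons per cell type were captured by laser 7 days after the later tracer. Each animal gave a pool of neurons labelled as sprouting and a pool labelled as non-sprouting. Both pools were hybridised together on a forward array, with sprouting neurons in Cy5, and again with the dyes exchanged. Each animal thus gave 1 log2 ratio per gene, with positive values for a higher signal in sprouting neurons. Between 69.8% and 95.5% of gene spots were well above background in the red channel and between 20.8% and 95.2% in the green, where the dye-swap array of day 21 replicate 4 was lowest. Across genes, which are not independent replicates, the forward and turned dye-swap ratios of an animal had correlations from 0.0519 in day 21 replicate 4 to 0.888 in day 7 replicate 1. The number of animals, 5 per day, limits the precision. Values are log2 ratios, given as mean ± SD over the 5 animals of a day unless another error or number is stated; the SE of a gene's ratio is the moderated one of the limma fit.

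The first comparison asked which genes differed between sprouting and non-sprouting neurons at day 7. Spp1, which encodes the secreted matrix protein osteopontin, had the highest ratio of the named genes, 2.67 ± 1.39 (SD, n = 5). No fold is given, since its spot was saturated on 2 of the 10 day 7 arrays. It was above 0 in all 5 animals, at 3.79, 3.37, 2.51, 3.36 and 0.33, and on 10 of the 10 arrays. Igf1, which encodes insulin-like growth factor 1, had a ratio of 1.19 ± 1.25 (SD, n = 5), with 3.37 in replicate 1 and 0.25 to 0.97 in the other 4 animals. In replicate 1 the lysozyme gene Lyz2 of macrophages had 4.22, while the median of microglia and macrophage markers was 0.069. Without replicate 1 the Igf1 ratio was 0.64, and other Igf1 probes had 0.82, 0.035 and 0.0022 over the 5 animals. Atrx, a chromatin remodeller, had a ratio of 0.32 ± 0.13 (SD, n = 5) and Lingo1, a co-receptor for myelin inhibitors of axon growth, 0.22 ± 0.12 (SD, n = 5), each above 0 in 5 animals.

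Cyp26b1, which breaks down retinoic acid, had the lowest day 7 ratio of the named genes, -0.81 ± 0.29 (SD, n = 5), and was below 0 on 10 of the 10 arrays. Adora1, the adenosine A1 receptor gene, had -0.32 ± 0.20 and Hmgcs1, an enzyme of cholesterol synthesis, -0.31 ± 0.12 (SD, n = 5). Another probe of Adora1 had a ratio of 0.036 and another of Hmgcs1 0.010. Sult4a1, a sulfotransferase, had -0.21 ± 0.065, Cltb, a clathrin light chain, -0.16 ± 0.065 and Csf2rb, a cytokine receptor subunit, -0.15 ± 0.047 (SD, n = 5). In the other direction Eif2s2, a subunit of a translation initiation factor, had 0.21 ± 0.077 (SD, n = 5). Each of these genes had 1 sign in the 5 animals, which the naming rule required.

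The ribosomal protein genes Rpl17 (0.44) and Rpl9 (0.28), Tpt1 (0.38), which encodes a translationally controlled protein, and Ppial4g (0.45) were also among the genes of smallest p at day 7, with signals at the scanner's ceiling. A spot of Rpl17 was saturated on 19 of the 20 arrays, of Ppial4g on 18, of Tpt1 on 11 and of Rpl9 on 10. The mean ratio of Rpl17 was -0.16 on forward and 1.04 on dye-swap arrays, and that of Ppial4g -0.10 on forward and 0.99 on dye-swap arrays. Rpl9 had -0.048 on forward and 0.60 on dye-swap arrays, and Tpt1 0.058 on forward and 0.69 on dye-swap arrays. Other probes had smaller day 7 ratios above 0, 0.11 and 0.13 for Tpt1 and 0.14 for Rpl17. Spp1 had 2.74 on forward and 2.61 on dye-swap arrays, Igf1 1.27 on forward and 1.11 on dye-swap arrays and Atrx 0.31 on forward and 0.32 on dye-swap arrays. Lingo1 differed more, with 0.13 on forward and 0.31 on dye-swap arrays.

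**Figure D1:**
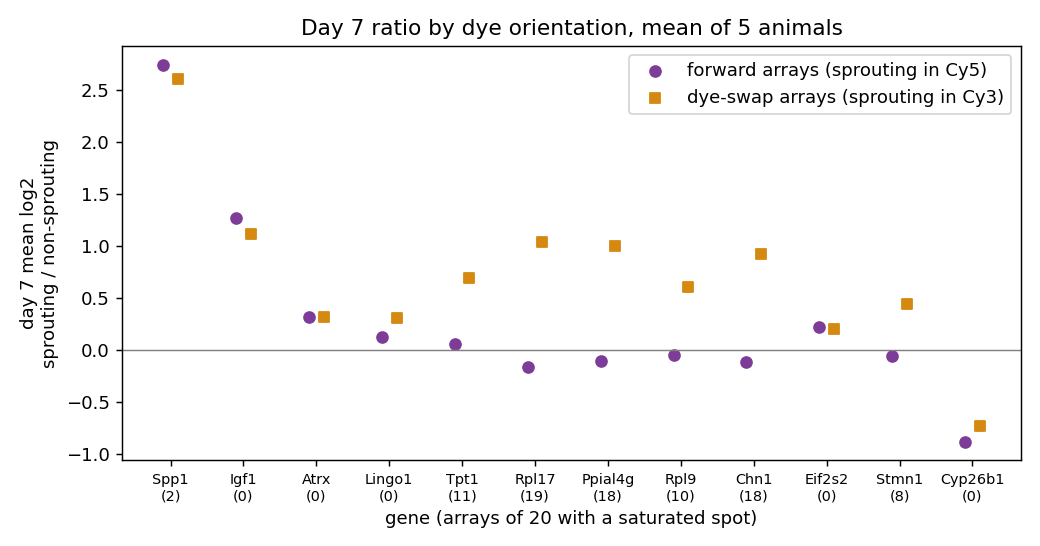
Mean day 7 log2 ratio of sprouting over non-sprouting neurons for 12 genes, as means over 5 animals on forward and on dye-swap arrays (vertical axis), by gene (horizontal axis), with the number of arrays of 20 that had a saturated spot in brackets. Spp1, Igf1, Atrx and Cyp26b1 had similar values in both orientations, while Rpl17 had -0.16 on forward and 1.04 on dye-swap arrays.

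In the limma fit over 31450 features, 0 passed an adjusted p of 0.05 at day 7. At an unadjusted p under 0.05 there were 1923, where chance gives about 1572 on average. Of these, 1072 had a higher and 851 a lower signal in sprouting neurons. The smallest adjusted p was 0.119. Spp1 had an adjusted p of 0.398, Cyp26b1 of 0.417, Atrx of 0.553, Lingo1 of 0.645 and Igf1 of 0.708 in limma. Of all features 3243, or 10.3%, had 1 sign in the 5 animals. Signs at random would give at most 6.25% on average, since features missing an animal could not count. Genes are not independent, so a single random outcome can lie above that average. Its spread was not computed, so the share is not read as above chance. With the 20 arrays entered singly, a dye effect and the animal as a random block, 13 features passed in limma, among them Spp1 and Cyp26b1, each with an adjusted p of 0.00434; over all alternatives this ranged up to 0.929 for Spp1 and 0.930 for Cyp26b1. That fit takes the arrays of an animal as partly separate observations. The dye-swap arrays alone, where the dye is not separated from the cell type, gave 15 features, Rpl17 among them.

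The second comparison asked the same at day 21. Atrx had the smallest p of the named genes, with a ratio of -0.53 ± 0.22 (SD, n = 5), below 0 on 10 of the 10 arrays. Neto2, an auxiliary subunit of kainate receptors, had -0.49 ± 0.22, Pclo, which encodes the active zone protein piccolo, -0.47 ± 0.31 and Pbx2, a homeodomain factor, -0.21 ± 0.075 (SD, n = 5). Lrg1, a secreted glycoprotein, had -0.20 ± 0.052 and Cyp2s1, a cytochrome P450, -0.14 ± 0.055 (SD, n = 5). In the other direction Id4, an inhibitor of helix-loop-helix factors, had 0.39 ± 0.21, G0s2, an inhibitor of triglyceride breakdown, 0.31 ± 0.14 and Abcc2, an export pump, 0.29 ± 0.18 (SD, n = 5). Leng1 had 0.16 ± 0.098, Mrpl18, a mitochondrial ribosomal protein gene, 0.13 ± 0.073 and Sh2d4b 0.11 ± 0.034 (SD, n = 5). All 12 had 1 sign in the 5 animals, which the naming rule required. On the forward arrays alone Sh2d4b had -0.091, and another probe of Mrpl18 had -0.0048. Igf1 had -0.031 ± 0.24 (SD, n = 5) and Lingo1 -0.012 ± 0.15 (SD, n = 5) at day 21, and both lay within 1 SD of 0. Spp1 had a value in 4 of the 5 day 21 animals, from -1.38 to 0.26. It was well above background on only 3 of 10 day 21 arrays for sprouting and 4 for non-sprouting neurons, so no difference from day 7 is drawn from these values.

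At day 21, 0 features passed in limma. At an unadjusted p under 0.05 there were 1505, where chance gives about 1572 on average. Of these, 584 had a higher and 921 a lower signal in sprouting neurons. The smallest adjusted p was 0.919, which was also that of Atrx, Neto2 and Pclo in limma. The share of features with 1 sign in the 5 animals was 5.67%, where signs at random would give at most 6.25% on average. Features missing an animal could not count but stayed in the total of 31450, and day 21 replicate 4 had values for about 28500. The share is therefore not read as below chance. With the 20 arrays entered singly 1 feature passed, Atrx, with a limma adjusted p of 0.000485; over all alternatives it ranged up to 1.

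**Figure D2:**
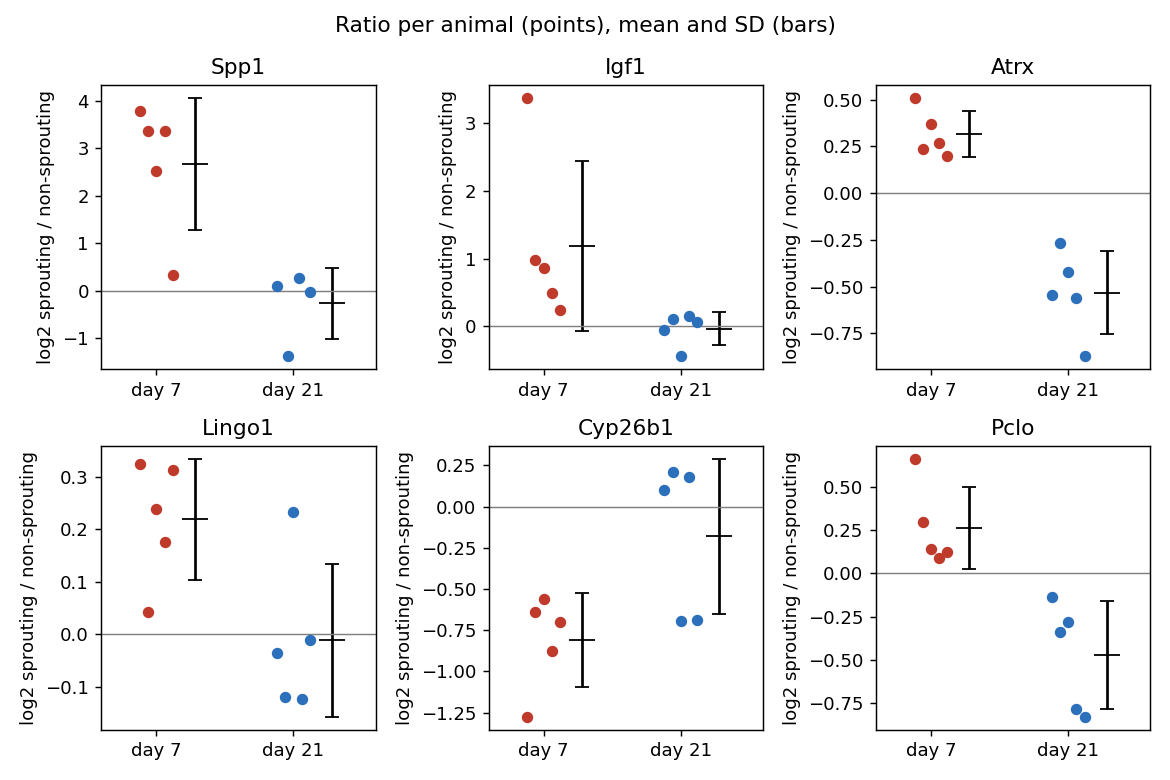
Log2 ratio of sprouting over non-sprouting neurons (vertical axis) in each animal at day 7 and day 21 (horizontal axis) for 6 genes, with 1 point per animal and bars for the mean and SD of each day. Atrx lies above 0 in the 5 day 7 animals and below 0 in the 5 day 21 animals, and Igf1 reaches 3.37 in 1 day 7 animal. Spp1 is drawn for both days, but its day 21 signal was not well above background on most arrays, so its days are not to be compared.

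The third comparison asked whether the ratio differed between the days, as day 21 minus day 7. Atrx had a difference of -0.85 ± 0.11 (SE), from 0.20 to 0.51 in the day 7 animals and from -0.87 to -0.27 in the day 21 animals. Of 3 Atrx probes, the other 2 had differences of -0.28 and -0.14, and the first of these had -0.12 at day 7. Igf1 had a difference of -1.22 ± 0.50 (SE); its other 3 probes had day 7 ratios of 0.82, 0.035 and 0.0022. Lingo1 had -0.23 ± 0.082, Efna5, an ephrin ligand gene, -0.12 ± 0.086 and Lmo4, a LIM domain factor, 0.0024 ± 0.18 (SE). The Lmo4 difference was below 0 without day 7 replicate 3 (-0.049) and in other alternatives. Pclo had a difference of -0.73 ± 0.16 (SE), above 0 in the 5 day 7 animals and below 0 in the 5 day 21 animals, and Sorcs3, a sorting receptor gene of neurons, -0.39 ± 0.083 (SE). Gosr2, a Golgi SNARE gene, had 0.35 ± 0.073, Or2ak5, an olfactory receptor gene, 0.22 ± 0.057 and Cdk11, a cyclin-dependent kinase gene, 0.21 ± 0.055 (SE). The last 2 were near background, with day 21 signals well above it on 5 (sprouting) and 4 (non-sprouting) of 10 arrays for Or2ak5 and on 7 and 4 for Cdk11, and over all alternatives their differences were 0.092 to 0.86 and 0.097 to 0.66, so their size is not known.

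In limma 0 differences passed over all features. At an unadjusted p under 0.05 there were 1308, fewer than the 1572 that chance gives on average. The adjusted p in limma was 0.339 for Atrx and 0.922 for Pclo and Igf1. A two-sided exact permutation of the days over the 10 animals gave p = 0.00794 for Atrx and Igf1, the smallest that these permutations can give, 0.0317 for Lingo1, 0.222 for Efna5 and 1 for Lmo4. It gave the same smallest p for Pclo and Sorcs3, which were tested after their values were seen. Adjusted over the list alone, Atrx (adjusted p = 5.39e-05) and Lingo1 (adjusted p = 0.0446) passed in limma among the 5 candidates recalled from the study. The study may have chosen these 5 genes on the same samples, so they are not independent evidence. With the 20 arrays entered singly 1 feature passed, Atrx, with a limma adjusted p of 6.24e-05; over all alternatives it ranged up to 1. A single scan batch held both days, with 2 day 7 animals and 1 day 21 animal, so the difference within it is also that with scan batch as a fixed block, at 1 animal against 2. It was -0.78 for Atrx, -0.42 for Igf1, -0.28 for Lingo1, 0.040 for Efna5, -0.11 for Lmo4, -0.24 for Pclo and -0.21 for Sorcs3. With that block Atrx kept an adjusted p of 0.0115 over the candidates in limma, and Lingo1 did not pass (adjusted p = 0.268), since its SE went from 0.082 to 0.18. For Gosr2 the difference was 0.12, for Cdk11 0.12 and for Or2ak5 0.18.

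The mean of both days asked which genes differed on average over the 2 days, which 1 day alone can bring about. The probe A_44_P222761, which has no gene name here and is named after its values were seen, had a ratio of -0.29 ± 0.030 (SE) and was lower in sprouting neurons of 10 of 10 animals. It was the 1 feature that passed in limma (adjusted p = 0.0490). At an unadjusted p under 0.05 there were 2041, where chance gives about 1572 on average. With any 1 of the other 9 animals left out 0 features passed in limma, against 1606 to 2083 at an unadjusted p under 0.05, and without day 21 replicate 5 3 features passed, this probe, Rpl26 and Lamp5. Of the named genes Tpt1, saturated on 11 arrays, had a mean ratio of 0.28 ± 0.042, Mrpl18 0.15 ± 0.024 and Sh2d4b 0.12 ± 0.020 (SE). Other Tpt1 probes had 0.11 and 0.13 at day 7 and 0.142 and 0.140 at day 21. Cltb had -0.12 ± 0.025, Rnf20, a histone ubiquitin ligase gene, -0.12 ± 0.026 and Kyat1, an aminotransferase gene, -0.11 ± 0.023 (SE). Each had 1 sign in 10 animals, which the naming rule required, and none passed the threshold. Of all features 124, or 0.394%, had 1 sign in 10 animals. Signs at random would give at most 0.195% on average, and the spread around that was not computed. On the dye-swap arrays alone 171 features passed in limma, against 5862 at an unadjusted p under 0.05. On the forward arrays alone 0 passed, against 4853, and Sh2d4b had -0.068. With 1 orientation the dye is not separated from the cell type, so these are not counts of genes that differ between the cell types. The mean ratios of the days had a Pearson r of 0.000371 and a Spearman rho of 0.0288 across genes. Exchanging the signs of animals in 512 patterns gave r from -0.334 to 0.334.

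Each of 26 gene lists was tested against all other genes with limma's camera at a preset correlation of 0.01, and with the correlation between genes estimated from the data 0 lists passed in any comparison. Cytosolic ribosomal protein genes had the smallest p, with 72 of 75 above 0 at day 7 and a median of 0.15 (adjusted p = 7.70e-16, or adjusted p = 0.821 with an estimated correlation). At day 21 67 of 75 were above 0, with a median of 0.076 (adjusted p = 3.25e-06, or adjusted p = 0.934 with an estimated correlation). Over all genes 0 members passed on either day in limma; adjusted over the list alone 4 passed at day 7, Rpl26, Rpl17, Rpl9, Rps6, and 0 at day 21, where Rpl30 had 0.19 ± 0.13 and Rps26 0.17 ± 0.20. Rpl26 and Rps6 were saturated on 10 arrays each, and at day 7 Rpl26 had -0.0030 on forward and 0.84 on dye-swap arrays and Rps6 -0.058 on forward and 0.61 on dye-swap arrays. Among day 7 animals the list median was 0.55 in replicate 1, 0.13 in replicate 5 and -0.00011 to 0.022 in the others. Without replicate 1 the day 7 median was 0.044, and without day 21 replicate 4 the day 21 median was 0.039 (adjusted p = 0.304), or 0.13 without replicate 5. With saturated spots set to missing, an alternative chosen after seeing the data, the day 7 median was 0.070. Over all alternatives the adjusted p was 2.15e-20 to 0.821 at day 7 and 1.20e-12 to 0.934 at day 21.

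Blood cell markers had 11 of 11 genes above 0 at day 7 and a median of 0.29 (adjusted p = 0.00170, or adjusted p = 0.821 with an estimated correlation). Camp, an antimicrobial peptide gene of neutrophils, had 0.29 ± 0.24 and Hbb-b1, a globin gene saturated on 9 arrays, 0.58 ± 0.60 (SD, n = 5). The blood cell median was 0.66 in day 7 replicate 1 and 0.024 to 0.058 in the others, and 0.019 without replicate 1 (adjusted p = 0.534, and 0.000322 to 0.821 over all alternatives). With no filter on dim probes it was 0.089 and with the stricter filter 0.58. Extracellular matrix and protease genes had 33 of 47 above 0 and a median of 0.073 (adjusted p = 0.00768, or adjusted p = 0.934 with an estimated correlation). Spp1 was the 1 member that passed adjusted over the list alone, and Mmp3, a matrix protease gene, had 0.62 ± 1.14 (SD, n = 5). Without replicate 1 the matrix median was -0.026 (adjusted p = 0.569, and 3.46e-05 to 0.934 over all alternatives). Apoptosis and p53 target genes had 23 of 30 above 0 and a median of 0.076 (adjusted p = 0.0102, or adjusted p = 0.821 with an estimated correlation). Tnfrsf1a, a TNF receptor gene, had 0.29 ± 0.43 (SD, n = 5), or 0.11 without replicate 1. Without replicate 1 the apoptosis median was 0.025 (adjusted p = 0.809, 0.0545 with no background correction, and 0.000135 to 0.821 over all alternatives).

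Markers of deep cortical layers had 13 of 15 genes below 0 at day 7 and a median of -0.092 (adjusted p = 0.00170, or adjusted p = 0.267 with an estimated correlation). The median was -0.15 without replicate 3, -0.16 with Feature Extraction ratios, -0.16 with the stricter filter and -0.060 with every probe tested. Tle4 had -0.13 ± 0.086 and Fezf2 -0.24 ± 0.23 (SD, n = 5), both transcription regulators of deep-layer neurons, and 0 members passed over all genes or adjusted over the list alone. The 5 candidates had a median of 0.22 at day 7 (adjusted p = 0.000124, or adjusted p = 0.232 with an estimated correlation), or 0.11 with every probe tested and 0.36 with Feature Extraction ratios. Lmo4 had 0.14 ± 0.21 and Efna5 0.078 ± 0.097 (SD, n = 5), or -0.034 on forward arrays alone. Of these 3 passed adjusted over the list alone at day 7, Lingo1, Igf1, Atrx, and 1 at day 21, Atrx, which is not independent evidence, and 0 over all genes. Left-out animals moved the number of lists that passed at day 7 from 6 to 3 without replicate 1 and 10 without replicate 2.

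**Figure D3:**
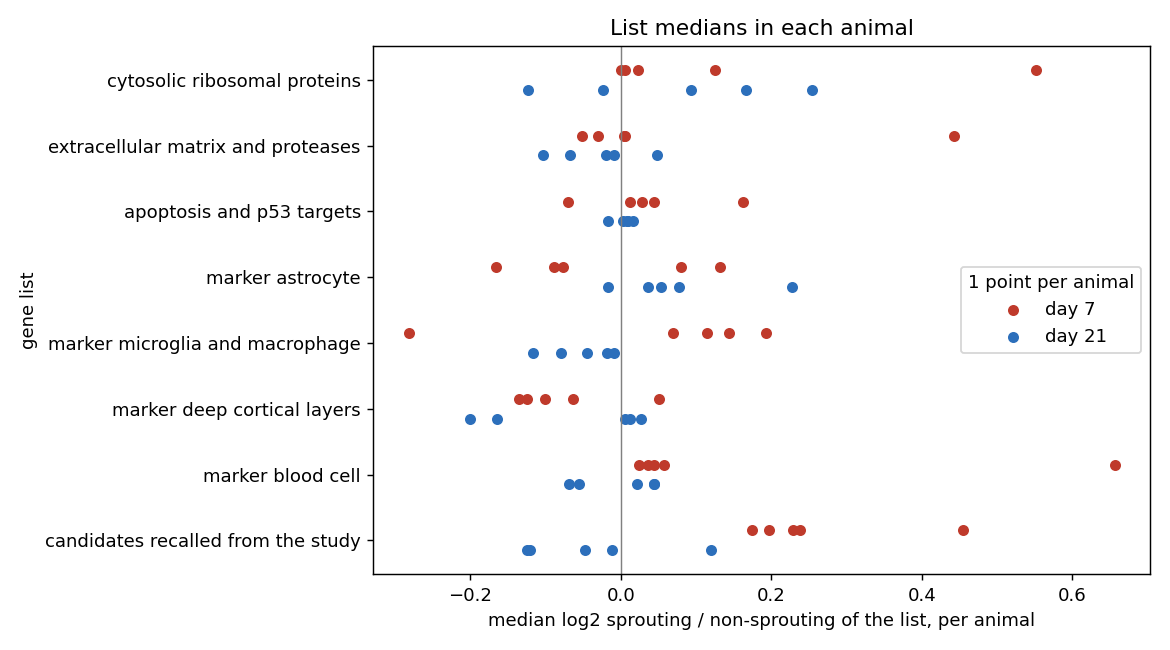
Median log2 ratio of sprouting over non-sprouting neurons (horizontal axis) in each animal at day 7 and day 21 for the gene lists (vertical axis) that passed in at least 1 comparison at the preset correlation, with 1 point per animal. Day 7 replicate 1 lies apart at 0.55 for ribosomal protein genes and 0.66 for blood cell markers.

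Between the days 6 lists passed at the preset correlation, 5 with lower ratios at day 21. Blood cell markers had a median difference of -0.28 (adjusted p = 0.0186, or adjusted p = 0.770 with an estimated correlation), and microglia and macrophage markers of -0.22 (adjusted p = 0.0148, or adjusted p = 0.770 with an estimated correlation). Extracellular matrix genes had -0.10 (adjusted p = 0.0148, or adjusted p = 0.770 with an estimated correlation), ribosomal protein genes -0.075 (adjusted p = 0.0148, or adjusted p = 0.857 with an estimated correlation) and the candidates -0.23 (adjusted p = 0.000536, or adjusted p = 0.282 with an estimated correlation). Astrocyte markers had 0.090 (adjusted p = 0.0377, or adjusted p = 0.770 with an estimated correlation). Within the scan batch that held both days the median difference was -0.058 for blood cell markers, -0.16 for microglia markers, 0.040 for matrix genes, -0.12 for ribosomal protein genes, -0.28 for the candidates and 0.051 for astrocyte markers. The blood cell result was lost without day 7 replicate 1 (adjusted p = 0.422), day 21 replicate 1 (0.0895) and day 21 replicate 2 (0.0686) and with no background correction (0.0619), and the matrix result without day 7 replicate 1 (0.955) and day 21 replicate 2 (0.0686). The ribosomal result was lost without day 21 replicate 1 (adjusted p = 0.197) or replicate 5 (0.651), and had the opposite direction without day 7 replicate 1 (0.402) and with saturated spots set to missing (0.666). The microglia result was lost without day 7 replicate 4 (adjusted p = 0.135). The astrocyte result was lost without day 7 replicate 1 (0.129), 3 (0.0644) or 4 (0.220), and without day 21 replicate 1 (0.0562), 3 (0.0890) or 4 (0.216). It was also lost with Feature Extraction ratios (0.136), scale normalization (0.104) and saturated spots set to missing (0.0518). Over all alternatives the adjusted p was 0.00497 to 0.770 for blood cell, 5.38e-07 to 0.770 for microglia and 0.00374 to 0.770 for astrocyte markers, 0.000131 to 0.955 for matrix genes, 9.05e-06 to 0.857 for ribosomal protein genes and 0.000146 to 0.282 for the candidates. Without day 7 replicate 1, 2 lists passed, and without day 21 replicate 1, 3.

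For the mean of both days ribosomal protein genes had a median of 0.12 (adjusted p = 1.76e-18, or adjusted p = 0.908 with an estimated correlation) and deep-layer markers -0.048 (adjusted p = 0.00879, or adjusted p = 0.726 with an estimated correlation; adjusted p = 0.16 without day 21 replicate 5). Over all alternatives it was 4.36e-22 to 0.908 for the former and 0.000423 to 0.726 for the latter. Adjusted over the list alone, Pclo passed among presynaptic genes and Atrx among chromatin regulators for the difference. Both calls were lost in limma with scan batch as a fixed block. There Pclo went from -0.73 to -0.24, while Atrx went from -0.85 to -0.78 and its SE from 0.11 to 0.16. For the mean Stmn1 among cytoskeleton genes, Chn1 among markers of glutamatergic neurons and 7 ribosomal protein genes passed, the last being Rpl26, Rpl17, Rps27a, Rps26, Rpl9, Rps6, Rps21. Of the 7 ribosomal protein genes all but Rps26 were saturated on 8 to 19 arrays, Rps27a on 14 and Rps21 on 8, and at day 7 Rps27a had -0.28 on forward and 0.91 on dye-swap arrays and Rps21 -0.033 on forward and 0.55 on dye-swap arrays, like the other saturated ones given above, so that saturation stays among the explanations of their ratios. Without day 7 replicate 2, 6 lists passed for the mean, and without day 21 replicate 5, 1.

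In the other lists 0 members passed over all genes, and the smallest camera adjusted p was 0.168 at day 7 and 0.0593 at day 21, the latter for astrocyte markers. Regeneration-associated genes had 25 of 35 above 0 at day 7 and 14 of 35 at day 21, with medians of 0.046 and -0.011. The day 7 median was 0.22 in replicate 1 and -0.014 without it. Their members of smallest p were Sox4 (0.13 ± 0.15) and Adcyap1, a neuropeptide gene (-0.21 ± 0.11), at day 7, and Smad1 (-0.48 ± 0.41) and Gap43, a growth cone protein gene (0.18 ± 0.087), at day 21; Gap43 was saturated on 12 arrays. Growth inhibitors and their receptors had medians of -0.0022 at day 7 and -0.031 at day 21, with Klf9 at 0.27 ± 0.44 at day 7 and Ptprs at -0.24 ± 0.46 and Rtn4rl2 at -0.11 ± 0.20 at day 21. Axon guidance genes had medians of -0.0056 at day 7 and -0.023 at day 21. Sema3a, a repulsive ligand gene, had 0.21 ± 0.17 in the 4 animals with a value and Plxnd1 0.30 ± 0.53 at day 7, or 0.089 without replicate 1, with -0.0049 at another Plxnd1 probe, and Robo2 -0.20 ± 0.25 and Sema6c -0.13 ± 0.11 at day 21; Sema6c had 0.020 on forward arrays alone. Growth factors and their receptors had medians of -0.00030 at day 7 and 0.0063 at day 21, with Bmp4 at 0.16 ± 0.13 at day 7 and Kdr at -0.27 ± 0.15 in 4 animals and Pdgfra at 0.48 ± 0.38 at day 21. Genes of the cytoskeleton and axonal transport had medians of 0.012 at day 7 and -0.021 at day 21, with Kif3a, a kinesin gene, at -0.22 ± 0.14 at day 7 and Nefl, the light neurofilament gene, at -0.36 ± 0.42 at day 21. Stmn1, a microtubule regulator, had 0.19 ± 0.10 and 0.11 ± 0.072, was saturated on 8 arrays, and at day 7 had -0.057 on forward and 0.44 on dye-swap arrays.

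Presynaptic genes had medians of 0.026 at day 7 and -0.017 at day 21, with the synapsin genes Syn2 (0.37 ± 0.26) and Syn3 (0.11 ± 0.059) at day 7 and Syn3 at 0.12 ± 0.079 at day 21. On forward arrays alone Syn3 had -0.019 and -0.14. Glutamate and GABA receptor genes had medians of -0.012 at day 7 and 0.019 at day 21, with Grin2b at 0.15 ± 0.13 and Gabra5 at -0.29 ± 0.17 at day 7 and Gria3 at -0.26 ± 0.34 and Gabrg3 at -0.11 ± 0.096 at day 21. Gabrg3 had 0.061 on forward arrays alone. Voltage-gated channel genes had medians of 0.024 at day 7 and -0.026 at day 21, with Scn3a at 0.20 ± 0.22 at day 7 and Scn3a at 0.23 ± 0.16 and Scn4b at -0.38 ± 0.23 at day 21, when another Scn4b probe had 0.049. Among immediate early genes, with medians of -0.0098 at day 7 and 0.0055 at day 21, the activity-induced genes Arc and Egr1 had -0.37 ± 0.24 and -0.22 ± 0.15 at day 7, each below 0 in 5 animals. Gadd45b had -0.29 ± 0.21 and Per1 -0.084 ± 0.054 at day 21, and Per1 0.044 on forward arrays alone. Inflammation and complement genes had medians of 0.010 at day 7 and -0.013 at day 21, with Tlr2 at 0.45 ± 0.39 and Cxcl2 at 0.25 ± 0.26 at day 7 and C1qa at -0.36 ± 0.25 and Cxcl12 at 0.40 ± 0.45 at day 21. Without day 7 replicate 1 Tlr2 had 0.29 and Cxcl2 0.15.

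Chromatin regulators had medians of -0.0034 at day 7 and 0.0080 at day 21. Adjusted over the list alone Atrx and Ehmt2, a histone methyltransferase gene (-0.16 ± 0.032), passed at day 7 and Atrx at day 21, when Hmgn2 had 0.11 ± 0.046. Heat shock and unfolded protein response genes had medians of -0.034 at day 7 and -0.020 at day 21, with Sel1l at 0.23 ± 0.15 and Hspa8, saturated on 8 arrays, at 0.18 ± 0.095 at day 7. Hspa9 had -0.14 ± 0.12 and Asns -0.12 ± 0.12 at day 21, when another Hspa9 probe had 0.033. Oxidative phosphorylation genes had medians of 0.0024 at day 7 and 0.019 at day 21 and 0.021 for the mean of both days, with Atp5mg, saturated on 7 arrays, at 0.14 ± 0.082 and Ndufs3 at -0.079 ± 0.017 at day 7, and Ndufb4 at 0.14 ± 0.15 and Ndufs6 at 0.12 ± 0.11 at day 21. On forward arrays alone the day 7 ratio was -0.12 for Hspa8 and -0.077 for Atp5mg, and other Hspa8 probes had 0.0072, 0.030 and -0.14. At day 21 matrix genes had a median of -0.040, with Adamts1 at 0.15 ± 0.14 and Hapln4 at -0.15 ± 0.22, and apoptosis genes -0.0063, with Xiap at -0.19 ± 0.18 and Birc5 at 0.11 ± 0.14 in 4 animals.

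Among markers of other cells, those of astrocytes had medians of -0.033 at day 7 and 0.055 at day 21, with Fgfr3 at 0.075 ± 0.034 and Slc7a10 at -0.080 ± 0.10 at day 7 and Gja1, a gap junction gene, at 0.20 ± 0.12 and Slc7a10 at -0.12 ± 0.14 at day 21. Another probe had 0.0026 for Slc7a10 at day 7 and -0.0085 for Gja1 at day 21. Oligodendrocyte markers had medians of -0.062 at day 7 and 0.027 at day 21, with a median of -0.69 in day 7 replicate 2 and a day 7 median of 0.12 without it. Mobp had -0.30 ± 0.57, with -0.078 and 0.059 at its other probes, and Olig2 -0.10 ± 0.14 at day 7, and Olig1 0.18 ± 0.21 at day 21. Microglia and macrophage markers had medians of 0.031 at day 7 and -0.037 at day 21, with Lyz2, a lysozyme gene, at 1.12 ± 1.83 (SD, n = 5) and Tyrobp at 0.47 ± 0.57 (SD, n = 4) at day 7 and C1qa and C1qb (-0.22 ± 0.18) at day 21. Endothelial markers had medians of 0.0089 at day 7 and -0.040 at day 21, with Abcg2 at -0.29 ± 0.18 and Slco1c1 at -0.23 ± 0.30 at day 7 and Vwf at -0.29 ± 0.16 at day 21, when another Vwf probe had 0.054. Interneuron markers had medians of -0.0034 at day 7 and 0.054 at day 21, with Cck at 0.25 ± 0.17 and Sst at -0.37 ± 0.84, or -0.047 without replicate 1, both neuropeptide genes, at day 7 and Vip at 0.66 ± 0.66 and Calb2 at 0.52 ± 0.73 at day 21.

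Markers of glutamatergic neurons had medians of 0.012 at day 7 and -0.036 at day 21. Chn1 (0.40 ± 0.20) passed adjusted over the list alone at day 7 but was saturated on 18 arrays and had -0.12 on forward and 0.92 on dye-swap arrays, with -0.21 at another probe. Cabp1 had -0.15 ± 0.30 at day 7 and -0.26 ± 0.18 at day 21, when Kcnv1 had 0.14 ± 0.43. Without day 21 replicate 5 Kcnv1 had -0.052. Upper-layer markers had medians of -0.055 at day 7 and 0.0079 at day 21, with Lhx2 at -0.13 ± 0.077 and Cux2 at -0.055 ± 0.067 at day 7 and Cartpt at -0.75 ± 0.64 and Pou3f3 at 0.30 ± 0.52 at day 21. At day 21 deep-layer markers had a median of -0.035, with Bcl11b at -0.44 ± 0.42 in 4 animals, 0.031 at another Bcl11b probe, and Ntsr1 at -0.11 ± 0.16. On forward arrays alone Ntsr1 had 0.021. Blood cell markers had -0.0098 at day 21, with Hbb-b1 at 0.21 ± 0.99, or -0.18 without replicate 4, and S100a8 at -0.040 ± 0.095, and the candidates -0.031, with Lmo4 at 0.14 ± 0.39 and Efna5 at -0.041 ± 0.17.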

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

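Among the tests below, those of the added microglia list, of the Atrx scan batch, of saturated spots, of short transcripts, of the spread over animals of ribosomal medians and of the splits on gene counts were chosen after the result was seen. In 20 of 174 groups of 4 or 5 animals, the highest or lowest animal stood apart from the others by Dixon's criterion, where chance gives about 1 in 20, or 8.7. That reference takes animals of equal spread and independent groups. The SD of ratios across genes was 0.37 and 0.27 in day 7 replicates 1 and 2, and 0.24 and 0.34 in day 21 replicates 4 and 5. In the others it was 0.13 to 0.17. All flags but that of Cabp1 fell on these wider animals, so a flag need not be particular to its gene or list. Day 7 replicate 1 stood apart for Igf1 (3.37) and Mmp3 (2.64) and for the medians of ribosomal protein genes (0.55), matrix genes (0.44), endothelial markers (0.25), blood cell markers (0.66) and the candidates (0.46). Day 7 replicate 2 stood apart for Syn3 (0.0038) and Mobp (-1.30) and for the medians of inflammation genes (-0.25), oligodendrocyte markers (-0.69) and microglia markers (-0.28), and day 7 replicate 5 for Cabp1 (0.38). At day 21 replicate 4 stood apart for Rtn4rl2 (-0.46), Gabrg3 (-0.28) and the median of glutamatergic markers (0.061), and replicate 5 for Nefl (-1.11), C1qb (-0.54), Kcnv1 (0.90) and Pou3f3 (1.22).

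Between the days, Atrx differed by -0.85 and Lingo1 by -0.23 in limma adjusted over the candidates alone, and Pclo by -0.73 adjusted over the presynaptic genes alone. With scan batch as a fixed block, an alternative chosen after seeing the data, the calls of Lingo1 (-0.23 ± 0.082 to -0.28 ± 0.18 SE) and Pclo (-0.73 ± 0.16 to -0.24 ± 0.11 SE) ended in limma. The first ended by a larger SE and the second by a smaller difference. Atrx no longer passed among chromatin regulators, with a similar difference and a larger SE (-0.85 ± 0.11 to -0.78 ± 0.16 SE). For the lists that passed at the preset correlation, the value is the median over genes of each gene's own difference between the days. It was -0.075 for ribosomal protein genes, -0.10 for matrix genes, 0.090 for astrocyte markers and -0.22 for microglia markers. For blood cell markers it was -0.28 and for the candidates -0.23. It need not equal the difference of the daily list medians, which for microglia markers were 0.031 at day 7 and -0.037 at day 21. With an estimated correlation 0 lists passed.

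Spp1 and Igf1 were above 0 in all 5 day 7 animals. A dye or single array effect is argued against, since both ratios were above 0 on 10 of 10 day 7 arrays. That cannot speak to a fault of the 1 probe used for Igf1, which was not tested. The other Igf1 probes had day 7 ratios of 0.82, 0.035 and 0.0022. RNA of activated microglia or macrophages in the sprouting capture stays open: the added list of 24 genes, 10 of them also in the fixed microglia list, had a mean animal median of 0.19 ± 0.16 (SE). The animal medians were 0.75 in replicate 1 and -0.27 to 0.18 in the others. In replicate 1 its genes reached 4.22 (Lyz2), 3.90 (Lgals3) and 3.81 (Gpnmb). Below 0 in that animal were Cd74 (-0.93), C1qa (-0.46), C1qb (-0.42), C1qc (-0.29) and Ctss (-0.18). In replicate 2 Spp1 had 3.37 while Lgals3 had -2.76 and Gpnmb -0.91, but 1 animal excludes nothing for the others. Higher expression in sprouting neurons, the difference the design names, may apply as well and was not tested apart from this.

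Atrx was above 0 in all 5 day 7 animals and below 0 in all 5 day 21 animals. Scan batch stays open: the difference was -0.78 within the only batch that held both days, which is also that with scan batch as a fixed block (± 0.16 SE, adjusted p = 0.0115 in limma over the 5 candidates, 0.106 over the chromatin regulators and 1 over all genes), while Igf1 went from -1.22 to -0.42 and Pclo from -0.73 to -0.24. This does not exclude scan batch, since it rests on 1 day 21 animal against 2, taken to vary like the others, and SDs within the days were 0.13 and 0.22. A fault of the 1 probe used stays open: the other Atrx probe nearest to 0 had a difference of -0.14, of the same sign and smaller. That probe had 0.080 at day 7 and -0.055 at day 21. The remaining Atrx probe had -0.12 at day 7 and -0.40 at day 21, so it was not above 0 at day 7. A difference between the days in sprouting neurons may apply as well, and the days were separate cohorts.

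The ribosomal protein list passed at the preset correlation, with 0.11 ± 0.060 (SE) over animal medians and 7 of 10 animals above 0, and the brightest genes had a median above 0 on dye-swap but not on forward arrays. Saturated spots may account for the brightest genes: 45 other features saturated on over 10 arrays had a median day 7 ratio of 0.45, with -0.16 on forward and 1.08 on dye-swap arrays. For the list saturation stays open at a median of 0.12 for the mean of both days over 33 members never saturated, as do short, abundant transcripts in general at 0.0042 for oxidative phosphorylation genes, since over animals these lay 0.069 ± 0.039 (SE) above and 0.049 ± 0.022 (SE) below 0.5 times the list's median, within the 2.26 SE of a t interval. The limits set beforehand for 1 animal (a limma camera adjusted p of 1.40e-08 without day 7 replicate 1) and for spot brightness (0% of 10000 brightness-matched lists as high) were met but wrong, as they left out the spread between animals: without that animal the mean was 0.058 ± 0.038 (SE), and the excess over matched lists 0.087 ± 0.060 (SE). Both stay open, as does correlation between these genes, estimated at 0.518 against the preset 0.01 (adjusted p = 0.908 with the estimate in limma's camera), and a difference between the cell types was not tested apart from them.

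With the cell types exchanged within animals, the 16 splits of 1 day are too few for a share under 0.05. At day 7 the real count of genes was 0 and the highest other 0 (16 splits as large), at an unadjusted p under 0.05 1923 and 1667 (1), and of lists 6 and 14 (14). At day 21 these were 0 and 0 (16), 1505 and 3275 (8), and 1 and 5 (10). For the difference, over 100 splits, chance cannot be excluded for genes (real 0, highest other 1, 100 as large), for those at an unadjusted p under 0.05 (1308, 2365, 33) or for lists (6, 14, 40). For the mean of both days the count of 1 gene was reached in 2 of 100 splits, the real one included (highest other 1), a share under 0.05. As 1 of several counts tested, chosen after the result was seen, it does not exclude chance. The call itself was lost without any 1 of 9 animals. Chance is also not excluded at an unadjusted p under 0.05 (2041, highest other 3008, 6 as large) or for lists (2, highest other 13, 87 as large). Some splits called several times the real number of lists, for which a structure of the samples or correlation between genes that the preset value leaves out may be the cause; neither was tested.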

How the results depend on the processing

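The settings with saturated spots missing, day 21 replicate 4 by its forward array alone, scan batch as a fixed block and missing values filled over all animals, and the list tests under other normalizations and left-out animals, were chosen after seeing the data. The cause of the changes listed was not tested unless the setting's construction shows it. In limma 0, 0 and 0 genes passed for day 7, day 21 and their difference, against 1923, 1505 and 1308 at an unadjusted p under 0.05, and 1 for the mean of both days. At day 7 the probe A_44_P222761 passed as the 1 feature without background correction, 1 in the authors' table and 1 with array weights. For the mean 0 passed with Feature Extraction ratios (1666 at an unadjusted p under 0.05), 0 with scale normalization (2176), 0 with the stricter filter (392, of 6037 tested), 0 with every probe (2198), 0 on forward arrays (4853), 0 with trend and robust eBayes (1177) and 0 with day 21 replicate 4 by its forward array (1976). With 20 arrays entered singly, counted as more observations, 13, 1, 1 and 11 passed for day 7, day 21, difference and mean. On dye-swap arrays, where the dye is not separated from the cell type, 15 passed at day 7 and 171 for the mean. Leaving out each animal gave 0 to 0, 0 to 0, 0 to 0 and 0 to 3 genes, the highest without day 21 replicate 5.

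Lists that passed numbered 6 at day 7, 1 at day 21, 6 for the difference and 2 for the mean, and 0, 0, 0 and 0 with an estimated correlation, as with fry (0 in each). At day 21 they numbered 2 without background correction, 3 with Feature Extraction ratios and 2 with missing values filled over all animals. Leaving out each animal gave 3 to 10, 0 to 4, 2 to 9 and 1 to 6 lists. The correlation of the days' ratios across genes ranged over -0.0953 to 0.166, the highest without day 21 replicate 5.

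Over all settings 53 values had the opposite direction, 52 of named genes, none of which had passed over all genes, and 1 of a list that had passed, the matrix genes at day 7. Lists that had not passed were left out of that count: 39 of their 45 day 7 and day 21 medians changed sign in at least 1 setting, 32 of them with an animal left out. Of the 53, those on forward arrays were, at day 7, Rpl17 -0.16, Ppial4g -0.10, Rpl9 -0.048, Stmn1 -0.057, Syn3 -0.019, Hspa8 -0.12, Atp5mg -0.077, Chn1 -0.12 and Efna5 -0.034. At day 21 they were Sh2d4b -0.091, Sema6c 0.020, Syn3 -0.14, Gabrg3 0.061, Per1 0.044 and Ntsr1 0.021, with Lmo4 -0.025 for the difference and Sh2d4b -0.068 and Efna5 -0.063 for the mean. Lingo1 at day 21 had 0.031 without background correction, 0.15 with Feature Extraction ratios, 0.015 on dye-swap arrays and 0.014 with replicate 4 by its forward array. Efna5 had 0.017, 0.12, 0.011 and 0.015 in those, 0.016 in the authors' table and 0.029 with array weights. Gabrg3 had 0.043 and Per1 0.027 with Feature Extraction ratios, Kcnv1 -0.0049 and Hbb-b1 -0.25 with array weights, and Ntsr1 0.0045 and S100a8 0.016 with replicate 4 by its forward array. The Lmo4 difference was -0.022 with scale normalization, -0.038 with array weights and -0.11 with scan batch as a fixed block, where Efna5 had 0.040. With animals left out values ranged over -0.11 to 0.14 for that difference, and at day 21 over -0.073 to 0.016 (Lingo1), -0.076 to 0.070 (Igf1), -0.081 to 0.025 (Efna5), -0.052 to 0.19 (Kcnv1) and -0.18 to 0.42 (Hbb-b1). Day 7 medians of lists that had passed moved by over 1.5 times in other settings too: ribosomal protein genes to 0.10 on forward arrays and 0.090 with array weights, matrix genes to 0.047 with the stricter filter and 0.037 with array weights, apoptosis genes to 0.043 on dye-swap arrays, and blood cell markers to 0.19 without background correction, 0.13 with array weights and 0.19 with saturated spots missing. Values with animals left out ranged over -0.0012 to 0.052 for Efna5 in the mean and -0.026 to 0.099 for the day 7 matrix median, the lowest without day 7 replicate 1. Of 143 ratios of named genes 57 moved by over 1.5 times without 1 animal, 28 of them to under 0.5 times their size or past 0. Without day 7 replicate 1 Lyz2 had 0.35, Mmp3 0.11, Tyrobp 0.20, Lmo4 0.060 and Olig2 -0.041 at day 7, and without replicate 2 Klf9 had 0.10 and Mobp -0.045. At day 21 Lmo4 had 0.029 and Birc5 0.042 without replicate 3, Robo2 -0.091, Hapln4 -0.072, Ntsr1 -0.047, Rtn4rl2 -0.018 and S100a8 -0.0071 without replicate 4, and Nefl -0.17, Ptprs -0.083 and Pou3f3 0.070 without replicate 5.

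With the replicate block 0 genes passed in limma for the difference (1150 at an unadjusted p under 0.05) and 0 for the mean (1482), which ended the call for the mean; it changed no other call of the genes in these contrasts, and the lists were not run with it. Animals of the same number in both days had correlations of 0.00774, 0.0371, -0.147, -0.195 and -0.0858, and none matched its own number best, so they share only a number. Of 143 named ratios 19 came from probes that neither cell type had well above background on all 10 arrays of a day, down to 5 arrays for Or2ak5 and for Syn3 at day 21, so their sizes are uncertain. Signal limits dim probes most on the dye-swap array of day 21 replicate 4, with 20.8% of spots well above background in green.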

Other observations

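The test of the added list was chosen after the Spp1 and Igf1 ratios were seen. Of 24 genes abundant in activated microglia and macrophages, 23 passed the filter. In day 7 animals the list median was 0.75, -0.27, 0.18, 0.18 and 0.11, and its mean over the day 21 animals was -0.038. Gpnmb, a membrane glycoprotein gene of phagocytes, had 1.29 ± 0.78 (SE over animals) at day 7 and 0.035 at day 21. Its day 7 values were 3.81 in replicate 1 and -0.91 to 1.95 in the others. Lgals3, a galectin gene, had 1.15 ± 1.16 (SE over animals) at day 7, from -2.76 in replicate 2 to 3.90 in replicate 1, and -0.11 at day 21. Lpl, a lipase gene, had 3.71 and Cst7, a cystatin gene, 2.80 in replicate 1, while the complement genes C1qa and C1qb had -0.46 and -0.42 in the same animal.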
